A study of Mus musculus with 4 samples.

How the data were processed

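RNA-seq libraries were made from LSK cells sorted from the bone marrow of 2 Metrn f/f and 2 Metrn cKO mice, per the labels' protocols. Per the same protocols, total RNA was extracted with TRIZOL, treated with DNase I and used for standard Illumina libraries. The 4 libraries therefore stand for separate mice. The submitters' processing notes name bcl2fastq 2.19, cutadapt 1.16.5, HISAT2 2.1, featureCounts 1.6.4, DESeq2 2.11.40.6 and the genome build mm10, without saying what each was used for. The annotation, the strand setting and the tool that wrote the values are not given in the sources used here.

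The authors deposited 1 table per library with a value for each of 47561 gene symbols. The file headers give only the library's name, so the unit was inferred from the values, which the deposited tables hold as FPKM (fragments scaled by transcript length and by mapped reads). They had decimals, were never negative and summed to different totals. FPKM values are shares of a library, so a few very abundant transcripts lower all others: the 20 most abundant genes took 8.71% of the sum in Metrn f/f 1, 17.3% in Metrn f/f 2, 21.9% in Metrn cKO 1 and 9.28% in Metrn cKO 2. Reads shared between near-identical genes can be split or lost, which leaves ribosomal protein, globin, immunoglobulin and Gapdh values uncertain. Gapdh had only 9.96 to 16.3 FPKM. Read totals could not be recovered. In RNAs under 200 nt, the value whose whole multiples held the most values was taken as 1 read in each library. It gave the relative depths of the libraries as a hint. Of these values 7.97% to 12.3% were whole multiples within 0.1%, a share that the choice itself favours. No interval for counting error was computed.

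Gene coordinates were taken from GENCODE release 21 for mouse on GRCm38, which is the assembly called mm10. Of the gene symbols, 34529 matched a GENCODE name and 44214 a RefSeq name. The RefSeq names were not used for coordinates.

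The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The planned test was for read counts, with limma on log values for normalized values, and the latter was used because the values were taken as FPKM. Genes with at least 1 FPKM in at least 2 libraries were kept (13148 genes). Metrn cKO was compared with Metrn f/f by a linear model of log2(FPKM + 1) with an intensity trend in the prior variance (limma 3.58.1 in R 4.3.3), 2-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale and understate the change of low genes. The standard error is limma's moderated error. Deposited values were not rescaled between libraries.

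Of the 33 gene lists, the sex-linked one was used only to check the animals, and 32 were tested by camera with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. Camera asks whether the genes of a list differ from all other genes. Camera with an estimated correlation and fry were run beside it. With an estimated correlation, camera has only the few degrees of freedom that 4 libraries leave, so it had little power here. The quiescence list had an estimated correlation of -0.025, below the preset 0.01, yet its unadjusted camera p rose from 8.37e-08 to 0.0271. A call lost in this way therefore does not show that correlation within the list undid it. For each pair of libraries, the median of each list was placed among 10000 random lists of the same size matched on mean expression. Xist was listed at 0.0441 FPKM in Metrn f/f 1 and at 0 in the other libraries, and Eif2s3y was between 26.6 and 37.8 FPKM in the 4 libraries, so no library differed in sex from the rest. The sex-linked list was measured for 4 of 6 genes.

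Named genes are Metrn and Lyz2, the genes with the largest change among those passing the test in each direction, the 4 members with the smallest p of each list called by camera and, in other lists, the 2 members with the highest mean. Because fewer than 5 genes passed in a direction, the 5 with the smallest p were named as not passing. These had a mean of at least 4 FPKM and both Metrn cKO values on the same side of both Metrn f/f values, and predicted, RIKEN, pseudogene, microRNA, small nucleolar RNA and sex-linked names were left out. Kit and Ly6a in the report were chosen after their values were seen.

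The test was run on simulated data for the comparison of Metrn cKO with Metrn f/f with 13148 genes, 200 of them changed, in 10 runs. With the spread of the real groups, 0% of changed genes were recovered at 2-fold, 4-fold, 8-fold and 16-fold (500 genes each). With the spread between the 2 most alike libraries, 100% were recovered at each fold, with 10.9 false calls per run. The first setting drew each gene from its raw spread in 2 libraries per genotype, a noisy estimate that can understate recovery. The second gave all genes 1 common spread, taken from Metrn f/f 1 and Metrn cKO 2, which differ in genotype. Neither figure therefore measures recovery in these data. A count of 0 genes in the real comparison is still not taken as evidence that genes did not differ. The list test on independent genes recovered a 2-fold shift of a list in 10 of 10 runs with 0 false calls. Genes of the real lists were not independent. Their estimated correlation ranged from -0.025 for the quiescence list to 0.93 for ribosomal proteins. The 0 false calls thus do not give the error of the list test in these data.

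The alternatives were the pseudocount, the filter, the threshold, a replicate block, each library left out in turn, the estimated correlation and fry. In the fits that leave out a library, the lone library was assumed to vary like the other group. A further 6 alternatives were chosen after the data were seen: rescaling to a fixed sum per library, upper quartile scaling, quantile normalization, removal of a trend with transcript length, crossed replicate numbers, and medians without Metrn f/f 2 and Metrn cKO 1. The alternatives planned for read counts were not run, since the values were taken as FPKM.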

Results

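RNA-seq was performed on LSK cells, the lineage-negative, Sca-1-positive, c-Kit-positive fraction of mouse bone marrow that holds hematopoietic stem cells and multipotent progenitors. Cells came from 12-week-old C57BL/6 mice. The 4 libraries formed 2 groups of 2 mice each. Metrn f/f mice carried a floxed Metrn gene and served as controls, and Metrn cKO mice carried the same floxed gene together with LysM, a driver of deletion in myeloid cells such as macrophages, monocytes and neutrophils. Each library had an expression value, taken as FPKM, for 47561 genes. The FPKM values summed to 392717 in Metrn f/f 1, 671802 in Metrn f/f 2, 562401 in Metrn cKO 1 and 412955 in Metrn cKO 2, and 12847, 12175, 12333 and 12996 genes reached 1 FPKM. Read totals were unknown. The value of 1 read in short RNAs gave relative depths of 1 for Metrn f/f 1, 0.823 for Metrn f/f 2, 0.681 for Metrn cKO 1 and 0.888 for Metrn cKO 2. These depths are a hint only, since 7.97% to 12.3% of the short RNA values were whole multiples of that value within 0.1%.

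The series asked how Meteorin, a secreted protein made by macrophages, acts on stem and progenitor cells. The targeted gene was compared first. Metrn (chromosome 17, positions 25793221 to 25797136 of GRCm38) had 29.3 FPKM in Metrn f/f 1, 66.3 in Metrn f/f 2, 42.3 in Metrn cKO 1 and 36.7 in Metrn cKO 2. The mean was 47.8 ± 26.1 FPKM in Metrn f/f and 39.5 ± 3.94 in Metrn cKO (SD, n = 2 each). The log2 fold change of -0.16 (SE 0.49) lay within the spread between mice. Deletion is driven in myeloid cells, so the Metrn level of LSK cells checks the genotype labels only in part. Lyz2, the driver locus and a lysozyme gene of myeloid cells (chromosome 10, positions 117277331 to 117282321), had 290 and 2406 FPKM in the Metrn f/f libraries and 2904 and 245 in the Metrn cKO libraries, with a log2 fold change of 0.01 (SE 1.45). Without Metrn f/f 2 the log2 fold change of Metrn was 0.415, and without Metrn f/f 1 it was -0.735. That of Lyz2 was -1.51 without Metrn f/f 1, 1.54 without Metrn f/f 2, -1.77 without Metrn cKO 1 and 1.79 without Metrn cKO 2.

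Transcripts of mature blood cells differed widely between mice of the same genotype. S100a8 and S100a9, calcium-binding proteins of neutrophils, together took 0.403% of all FPKM in Metrn f/f 1, 3.15% in Metrn f/f 2, 6.60% in Metrn cKO 1 and 0.298% in Metrn cKO 2. Globin genes took 1.01%, 5.57%, 5.58% and 0.774%. C1qb, a complement component of macrophages, had 8.01, 297, 48.4 and 8.54 FPKM, and Cd74, the invariant chain of antigen-presenting cells, had 161, 955, 1008 and 113 FPKM. The list medians of LSK sort markers and HSC-enriched genes ran the other way, with single genes against it. Relative to each gene's mean, the median log2 level was 0.31, -0.29, -0.55 and 0.43 for the sort markers and 0.41, -0.18, -0.83 and 0.49 for the HSC-enriched genes. The stem cell factor receptor gene Kit, a marker of the sort, had 108, 24.8, 25.9 and 116 FPKM in the same order, and the adhesion receptor gene Adgrg1 had 406, 133, 128 and 421. Against this order, Ly6a, which encodes the sort marker Sca-1, had 37.2, 83.2, 48.4 and 38.2 FPKM, and the stem cell marker genes Pdzk1ip1 and Ifitm1 were highest in Metrn f/f 2, at 41.6 and 315 FPKM. Between Metrn f/f 1 and Metrn cKO 2, 179 of the 13148 tested genes differed by at least 2-fold (98 higher and 81 lower in Metrn cKO 2). Between the Metrn f/f libraries 4681 genes did so, and between the Metrn cKO libraries 2514.

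**Figure D1:**
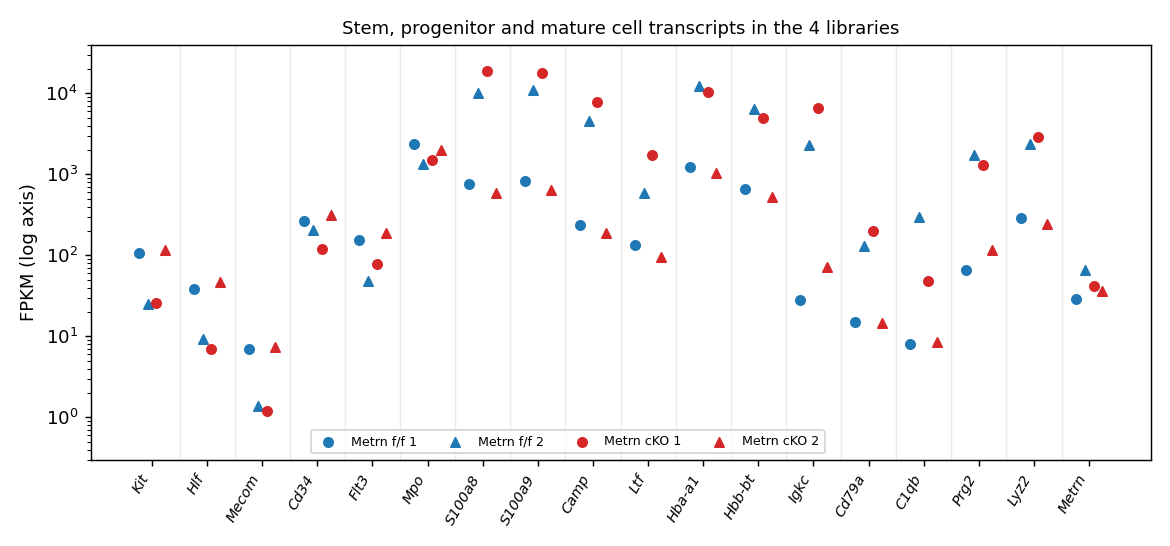
FPKM on a log axis of stem, progenitor and mature cell genes, with Lyz2 and Metrn, in the 4 libraries; each point is 1 library, with Metrn f/f in blue, Metrn cKO in red, circles for replicate 1 and triangles for replicate 2. Kit lies at 24.8 and 25.9 FPKM in Metrn f/f 2 and Metrn cKO 1 and at 108 and 116 in the other libraries, while Lyz2 lies at 2406 and 2904 against 290 and 245. The genes shown were picked by hand, and Ly6a, Pdzk1ip1 and Ifitm1, which ran against this order, are not among them.

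The main comparison asked which genes differ in LSK cells when Metrn is deleted in myeloid cells. No gene passed: 0 genes were higher and 0 lower in Metrn cKO by limma at an adjusted p of 0.05, and the smallest adjusted p was 1.00. At an unadjusted p under 0.05 there were 39 genes (8 higher, 31 lower), against 657.4 that chance gives. Both Metrn cKO values exceeded both Metrn f/f values in 829 genes (6.31%) and lay below them in 754 (5.73%), where chance gives 16.7% in each direction. Genes named here had the smallest p in each direction among those with a mean of at least 4 FPKM, groups that did not overlap and an allowed name. Their unadjusted p by limma reached 0.0902, for Esyt2, so they are not the genes nearest to the threshold. Alox15, a lipoxygenase that oxidises arachidonic and linoleic acid (chromosome 11, positions 70344152 to 70352031), had 1.47 ± 0.345 FPKM in Metrn f/f and 27.9 ± 5.29 in Metrn cKO (SD, n = 2 each), with a log2 fold change of 3.54 (SE 0.49). Larp4b, an RNA-binding protein, had 6.71 ± 0.931 and 18.6 ± 2.49 FPKM, and the membrane contact protein gene Esyt2 had 5.53 ± 4.64 and 12.9 ± 2.28. The immunoglobulin genes Ighg2c and Igkv5-48 had log2 fold changes of 2.82 (SE 1.04) and 4.36 (SE 1.72), and both were listed at 0 in Metrn f/f 1. With each library left out in turn these ranged from 1.20 to 4.44 and from 2.105 to 6.62. On the lower side, Nr4a1, an orphan nuclear receptor induced within minutes of stimulation (chromosome 15, positions 101254269 to 101274795), had 142 ± 95.7 FPKM in Metrn f/f and 7.60 ± 3.15 in Metrn cKO, with a log2 fold change of -3.93 (SE 0.59). Klf6 and Egr1, zinc finger transcription factors, had log2 fold changes of -1.50 (SE 0.44) and -1.94 (SE 0.64). Socs3, an inhibitor of cytokine signalling, had -2.11 (SE 0.62) and Fosb, an AP-1 subunit, -2.03 (SE 0.66). Without Metrn cKO 1 5 genes were called lower, all of them immunoglobulin segments. Without Metrn cKO 2 32 genes were called higher and 2 lower, of which 30 were immunoglobulin genes and 1, Nr4a1, was an immediate early gene.

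Immediate early genes, which are induced within minutes by stimulation, handling or dissociation, lay lower in both Metrn cKO libraries. Of the 24 measured members, 19 had both Metrn cKO values below both Metrn f/f values and 0 had both above. The median log2 fold change of the list was -1.42 (camera, adjusted p = 9.83e-48). The call was lost at adjusted p = 0.621 with an estimated correlation, a test that so few libraries leave with little power. No member passed over all genes, and 1 member, Nr4a1, passed when adjusted over the list alone (adjusted p = 0.00999). The median of Metrn cKO 1 minus Metrn f/f 1 was -1.09 and that of Metrn cKO 2 minus Metrn f/f 1 was -0.53. Against Metrn f/f 2 the medians were -2.27 and -1.78. Each lay below all 10000 random lists matched on expression. Libraries of the same genotype differed beyond all random lists too: the median of Metrn f/f 2 minus Metrn f/f 1 was 1.32 and that of Metrn cKO 2 minus Metrn cKO 1 was 0.57. In the closest pair, 23 of the 24 genes were lower in Metrn cKO 2 than in Metrn f/f 1. The list kept its call and direction when each library was left out in turn, with adjusted p between 1.01e-35 and 2.27e-18.

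**Figure D2:**
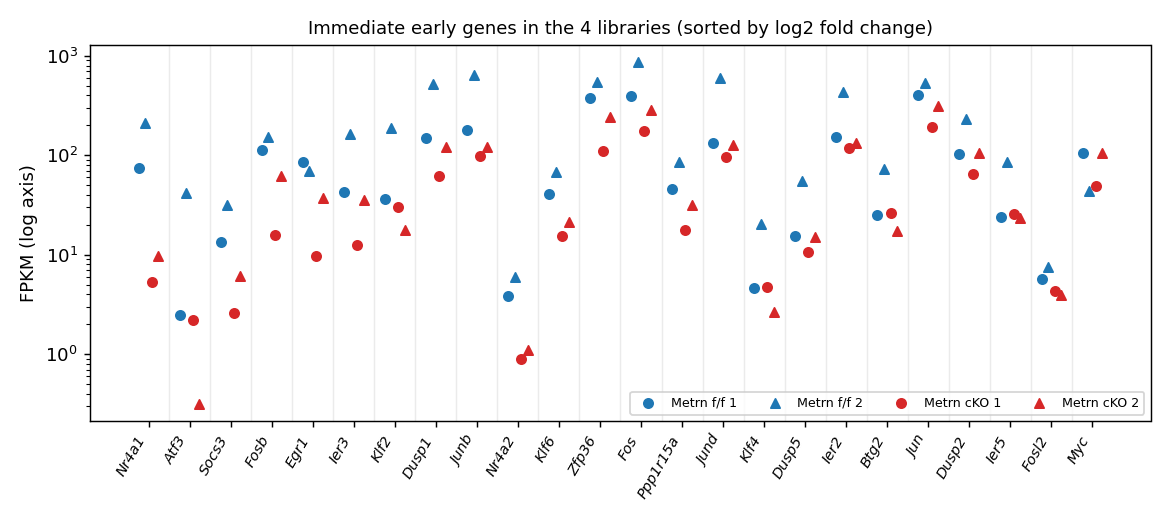
FPKM on a log axis of the 24 measured immediate early genes, sorted by log2 fold change; each point is 1 library, with Metrn f/f in blue, Metrn cKO in red, circles for replicate 1 and triangles for replicate 2. In 19 of the genes both Metrn cKO points lie below both Metrn f/f points, and Nr4a1 has 74.7 and 210 FPKM in Metrn f/f against 5.37 and 9.83 in Metrn cKO.

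NF-kB targets, which hold cytokines and feedback inhibitors of inflammation, were called lower (median log2 fold change -0.38, adjusted p = 2.94e-08), and 8 of 36 members had both Metrn cKO values below both Metrn f/f values. The call was lost at adjusted p = 0.693 with an estimated correlation and at adjusted p = 0.96 without Metrn f/f 2. Metrn f/f 2 stood apart in this list, by a median of 1.10 above Metrn f/f 1, while Metrn cKO 1 and Metrn cKO 2 differed from Metrn f/f 1 by 0.06 and -0.13. Macrophage and monocyte genes moved with it, with Metrn f/f 2 at a median of 2.79 above Metrn f/f 1. Its leading members had unadjusted p under 0.05 and did not pass. Nfkbiz, an atypical inhibitor of NF-kB, had 25.8 ± 2.82 FPKM in Metrn f/f and 9.93 ± 5.84 in Metrn cKO, and the ubiquitin-editing enzyme gene Tnfaip3 had 20.8 ± 15.5 and 4.94 ± 0.915. Ier3 had 104 ± 86.5 and 23.9 ± 15.9 FPKM, and the chemokine gene Ccl3 had 157 ± 138 and 36.0 ± 19.0. The list of cell cycle inhibitors and quiescence genes was called lower (adjusted p = 4.47e-07), with a median of -0.05, a mean of -0.54 and 7 of 24 members below in both Metrn cKO libraries. This call was lost at adjusted p = 0.621 with an estimated correlation. Its leading members were Nr4a1, Klf6, Egr1 and the AP-1 gene Junb (407 ± 324 and 111 ± 16.1 FPKM), and 1 member, Nr4a1, passed when adjusted over the list alone. Without the 7 genes it shares with the immediate early list its median was 0.08 (adjusted p = 0.70), a comparison chosen after the data were seen. Targets of p53 were called lower (median -0.10, adjusted p = 0.00111, 4 of 26 members below in both Metrn cKO libraries), and the call was lost at adjusted p = 0.621 with an estimated correlation, at 0.098 without Metrn cKO 2, at 0.43 without Metrn f/f 2 and at 0.119 with no filter on low values. Plk2, a stress-inducible kinase, had 10.2 ± 8.05 and 1.64 ± 0.0821 FPKM. Cdkn1a, the p21 cell cycle inhibitor, had 29.9 ± 14.5 and 12.7 ± 1.09, and Btg2 and Dcxr had log2 fold changes of -0.99 (SE 0.58) and -0.75 (SE 0.59).

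Stem cell and lineage genes were compared next. HSC-enriched genes were called lower (median log2 fold change -0.26 over 29 genes, adjusted p = 0.00105), a call lost at adjusted p = 0.693 with an estimated correlation. Only 1 of them, the homeobox gene Nkx2-3, had both Metrn cKO values below both Metrn f/f values (14.8 ± 1.23 and 8.34 ± 6.66 FPKM). Metrn cKO 1 lay below Metrn f/f 1 by a median log2 difference of -1.28, while Metrn cKO 2 differed from Metrn f/f 1 by 0.09. Pdzk1ip1, Ifitm1 and Esam, surface markers enriched in stem cells, had log2 fold changes of -0.98 (SE 0.73), -0.81 (SE 0.61) and -0.73 (SE 0.72). Multipotent and lymphoid priming genes were called higher (median 0.49 over 22 genes, adjusted p = 0.00111), a call lost at adjusted p = 0.649 with an estimated correlation. The list median was higher in each Metrn cKO library than in each Metrn f/f library. In this list 5 genes had both Metrn cKO values above both Metrn f/f values and 1 had both below. Dntt, the terminal transferase of early lymphoid cells, had 178 ± 14.8 FPKM in Metrn f/f and 310 ± 110 in Metrn cKO. The recombinase genes Rag1 and Rag2 had 1.49 ± 0.561 and 5.65 ± 5.38 FPKM and 1.74 ± 0.0349 and 5.08 ± 3.39 FPKM, and Arpp21 had 3.57 ± 1.03 and 7.29 ± 3.71. Metrn cKO 1 carried most of this, with Rag1 at 9.45 FPKM against 1.84 in Metrn cKO 2 and Rag2 at 7.48 against 2.69. B and plasma cell genes moved with it, with Metrn cKO 1 at a median of 2.92 above Metrn f/f 1 and Metrn cKO 2 at 0.21. Megakaryocyte genes were called lower (median -0.15 over 17 genes, adjusted p = 0.00368; adjusted p = 0.693 with an estimated correlation), with 1 gene, Thbs1, below in both Metrn cKO libraries (5.98 ± 2.84 and 1.13 ± 0.639 FPKM). The platelet chemokine gene Pf4 had 36.8 ± 37.3 and 8.13 ± 3.50 FPKM, and the platelet glycoprotein genes Gp5 and Gp9 had log2 fold changes of -0.63 (SE 0.59) and -0.60 (SE 0.63). Erythroid genes were called lower (median -0.80 over 22 genes, adjusted p = 1.86e-09), and this call too was lost at adjusted p = 0.693 with an estimated correlation. Metrn f/f 2 stood above Metrn f/f 1 by a median of 2.57, and Metrn cKO 1 stood above Metrn f/f 1 by 0.50. The transcription factor genes Gata1 and Klf1 had 17.8 and 36.2 FPKM in Metrn f/f 2 and at most 5.31 in the other libraries, and Aqp1 and Slc4a1, a water channel and an anion exchanger of red cells, had 47.5 and 45.2 FPKM in Metrn f/f 2 and at most 9.80 in the others. The erythroid list was called higher without Metrn f/f 2 (adjusted p = 0.030). The other calls were lost without Metrn cKO 1, at adjusted p = 0.41 for the HSC-enriched genes with the direction reversed, 0.41 for the megakaryocyte genes and 0.96 for the multipotent and lymphoid genes with the direction reversed, and without Metrn f/f 1, at adjusted p = 0.18, 0.21 and 0.19. With no filter on low values the HSC-enriched and megakaryocyte calls were lost at adjusted p = 0.131 and 0.123.

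Granulocyte-monocyte differentiation genes were not called (median -0.05 over 28 genes, adjusted p = 0.356). Elane, a granule protease of promyelocytes, had 2108 ± 679 FPKM in Metrn f/f and 1646 ± 479 in Metrn cKO, and the myeloperoxidase gene Mpo had 1864 ± 724 and 1749 ± 350. The list was called lower without Metrn cKO 1 (adjusted p = 8.3e-06) or Metrn f/f 1 (adjusted p = 0.014) and higher without Metrn cKO 2 (adjusted p = 0.00079) or Metrn f/f 2 (adjusted p = 0.0048). The sort markers of LSK cells were not called (median -0.18 over 8 genes, adjusted p = 0.287), with Cd34 at 236 ± 42.4 and 215 ± 137 FPKM and Flt3 at 101 ± 73.8 and 134 ± 78.5. They were called lower without Metrn cKO 2 (adjusted p = 0.036).

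Cell cycle genes were called higher in Metrn cKO. Both calls, G2/M (adjusted p = 1.11e-05) and S phase (adjusted p = 0.00271), were lost at adjusted p = 0.693 with an estimated correlation. For G2/M genes the median log2 fold change was 0.35 over 54 genes, and 7 genes had both Metrn cKO values above both Metrn f/f values against 1 below. For S phase genes the median was 0.19 over 42 genes, with 7 above and 2 below. The list medians of Metrn f/f 2 lay below those of Metrn f/f 1, by -0.38 for G2/M and -0.43 for S phase. Mki67, a proliferation marker, had 35.0 ± 33.9 FPKM in Metrn f/f and 49.7 ± 0.646 in Metrn cKO. The mitotic genes Kif2c, Lbr and Ttk had log2 fold changes of 0.62 (SE 0.47), 0.46 (SE 0.41) and 0.61 (SE 0.55). The replication genes E2f8, Wdr76, Exo1 and Uhrf1 had 0.80 (SE 0.52), 0.87 (SE 0.61), 0.75 (SE 0.59) and 0.53 (SE 0.42). Between Metrn cKO 2 and Metrn f/f 1 the medians were -0.07 for G2/M and -0.01 for S phase. The calls were also lost without Metrn f/f 2, at adjusted p = 0.09 for G2/M and 0.35 for S phase, and without Metrn cKO 1, at 0.84 and 0.49.

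Ribosomal protein genes were called lower (median log2 fold change -0.36 over 76 genes, adjusted p = 9.01e-08), as were oxidative phosphorylation genes (median -0.29 over 59 genes, adjusted p = 3.50e-07) and antioxidant defence genes (median -0.16 over 35 genes, adjusted p = 0.0110). All 3 calls were lost at adjusted p = 0.693 with an estimated correlation. These lists stood high in Metrn f/f 2, by medians of 1.37, 1.27 and 0.71 above Metrn f/f 1. In the pair of Metrn cKO 2 and Metrn f/f 1 the medians were 0.23, 0.09 and 0.07. Rpl7a was the only ribosomal protein gene with both Metrn cKO values below both Metrn f/f values (512 ± 229 and 238 ± 10.7 FPKM). Rpl17, Rps27a and Rpl18 had log2 fold changes of -1.34 (SE 0.87), -0.55 (SE 0.64) and -0.64 (SE 0.79). Reads of ribosomal protein genes can be shared with pseudogenes, so these levels are uncertain. The respiratory chain genes Ndufs3, Ndufa7 and Ndufs7 had -0.58 (SE 0.46), -0.55 (SE 0.57) and -0.44 (SE 0.46), and the ATP synthase gene Atp5g1 had -0.55 (SE 0.54). Among antioxidant genes, Gclm of glutathione synthesis had 30.1 ± 8.09 and 20.8 ± 0.903 FPKM, and the regulator Nfe2l2 had a log2 fold change of 0.41 (SE 0.38). Gpx4, a lipid peroxide reductase, had 282 ± 187 and 161 ± 21.6, and Gsta4 had a log2 fold change of -0.78 (SE 0.65). Without Metrn f/f 2 these lists were called higher (adjusted p = 1.5e-11, 4.4e-13 and 0.00029). Without Metrn cKO 2 the calls were lost at adjusted p = 0.45, 0.93 with the direction reversed and 0.89. With the trend in transcript length removed, the oxidative phosphorylation and antioxidant calls were lost at adjusted p = 0.0667 and 0.138, and the antioxidant call was also lost with no filter on low values and with quantile normalization, at adjusted p = 0.236 and 0.148.

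Phospholipase C and calcium signalling genes were called higher (median 0.28 over 31 genes, adjusted p = 0.000618), a call lost at adjusted p = 0.693 with an estimated correlation. Metrn f/f 2 stood apart in this list, below Metrn f/f 1 by a median of -0.95, while Metrn cKO 2 differed from Metrn f/f 1 by 0.03. In that library long transcripts were low in general, with a median of -1.31 relative to Metrn f/f 1 for those over 5000 nt. The list nevertheless kept its call and direction with the trend in transcript length removed. Of the genes of this list 0 had both Metrn cKO values on 1 side of both Metrn f/f values. Plcg2, a phospholipase C, had 72.4 and 28.6 FPKM in Metrn f/f and 65.0 and 75.9 in Metrn cKO. The diacylglycerol kinase gene Dgkz had a log2 fold change of 0.86 (SE 0.51), the protein kinase C gene Prkcb of 0.70 (SE 0.66) and the calcium channel gene Orai2 of 0.48 (SE 0.47). The call was also lost without Metrn f/f 2 (adjusted p = 0.43, direction reversed) and without Metrn cKO 2 (adjusted p = 0.11). Genes of NADPH oxidase and production of reactive oxygen species were not called (median 0.15 over 13 genes, adjusted p = 0.0852). Its member Alox15 passed when adjusted over the list alone (adjusted p = 0.00322), and 0 genes did so in the lists other than this, the immediate early and the quiescence list. Cyba, a subunit of the phagocyte oxidase, followed the neutrophil genes with 110, 539, 488 and 105 FPKM in Metrn f/f 1, Metrn f/f 2, Metrn cKO 1 and Metrn cKO 2. This list was called higher without Metrn cKO 2 (adjusted p = 3.2e-08) or Metrn f/f 2 (adjusted p = 2.6e-06), and with scaling to a fixed sum (adjusted p = 0.00539) or quantile normalization (adjusted p = 0.00535).

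Further lists of cell functions were not called. Adhesion and homing genes had a median of 0.10 over 35 genes (adjusted p = 0.363), with Rac2 at 188 ± 75.5 and 214 ± 109 FPKM. Interferon response genes had a median of -0.00037 over 46 genes (adjusted p = 0.481), with B2m at 1725 ± 857 and 1273 ± 111 FPKM and H2-K1 at 1064 ± 224 and 820.3 ± 131. Unfolded protein response genes had a median of -0.04 over 27 genes (adjusted p = 0.102), with the chaperone genes Calr at 561 ± 66.2 and 502 ± 13.9 and Hspa5 at 233 ± 46.0 and 206 ± 52.8. Myc targets and ribosome biogenesis genes had a median of -0.02 over 34 genes (adjusted p = 0.0700), with Npm1 at 442 ± 111 and 337 ± 52.2 and Fbl at 184 ± 40.8 and 150.5 ± 5.24. Cholesterol synthesis genes had a median of 0.09 over 23 genes (adjusted p = 0.360), with Srebf2 at 44.3 ± 22.4 and 56.2 ± 16.9 and Fdps at a log2 fold change of -0.04 (SE 0.51). In the glycolysis, apoptosis and heat shock lists the median, mean and test differed in sign or lay near 0. Glycolysis genes had a median of 0.01 over 22 genes (test direction lower, adjusted p = 0.637), with Pkm at 450.2 ± 16.5 and 508 ± 116 and Aldoa at 359 ± 142 and 310 ± 93.6. Apoptosis regulators had a median of 0.05 and a mean of -0.02 over 25 genes (adjusted p = 0.660), with Mcl1 at 118 ± 40.0 and 77.2 ± 2.84 and Bax at 82.7 ± 58.5 and 55.7 ± 5.91. Heat shock genes had a median of -0.000037 and a mean of 0.05 over 18 genes (adjusted p = 0.598), with Hsp90ab1 at 922 ± 181 and 943 ± 122 and Hspa8 at 820 ± 247 and 828 ± 238. Calls appeared without Metrn cKO 1 for unfolded protein response genes (lower, adjusted p = 0.011) and heat shock genes (lower, 0.032), without Metrn cKO 2 for heat shock (higher, 0.039), adhesion (higher, 0.042) and Myc target genes (lower, 0.034), and without Metrn f/f 2 for Myc target genes (lower, 0.0016). With scaling to a fixed sum the unfolded protein response genes were called lower (adjusted p = 0.0413), and with the length trend removed the Myc target genes were (adjusted p = 0.0255).

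Markers of other cell types that the gate could hold were compared in the same way. Macrophage and monocyte genes were called lower (median log2 fold change -0.62 over 19 genes, adjusted p = 0.000760), and B and plasma cell genes were called higher (median 0.54 over 18 genes, adjusted p = 0.00731). With an estimated correlation these calls were lost at adjusted p = 0.693 and adjusted p = 0.706. Of these genes 0 of 19 and 1 of 18 had both Metrn cKO values on 1 side of both Metrn f/f values. The lysosomal glycoprotein gene Cd68 had 80.4 FPKM in Metrn f/f 2 and a log2 fold change of -0.83 (SE 0.89), the heme oxygenase gene Hmox1 had at most 19.4 outside Metrn f/f 2 and a log2 fold change of -0.98 (SE 1.17), and the lipopolysaccharide co-receptor gene Cd14 had 23.5 in Metrn f/f 2 and at most 4.25 in the others. Ighm, the heavy chain of immunoglobulin M, had 3426 FPKM in Metrn cKO 1 and at most 727 in the others, and the B cell transcription factor genes Pax5 and Ebf1 had 8.09 and 9.30 in Metrn cKO 1 and at most 1.51 and 1.88. Sdc1, a plasma cell marker, had 9.21 ± 1.18 and 11.9 ± 1.41 FPKM. The macrophage list was called higher without Metrn f/f 2 (adjusted p = 2.2e-09) and was not called without Metrn cKO 2 (adjusted p = 0.80), and the B cell list was called lower without Metrn cKO 1 (adjusted p = 2.4e-11) and was not called without Metrn f/f 1 (adjusted p = 0.12) or with no filter on low values (adjusted p = 0.134).

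Neutrophil genes were not called (median 0.13, mean -0.07, test direction lower, adjusted p = 0.287 over 19 genes). S100a9 had 5983 ± 7292 FPKM in Metrn f/f and 9364 ± 12329 in Metrn cKO, and the list median of Metrn f/f 2 stood 3.02 above that of Metrn f/f 1. Dendritic cell genes were not called (median -0.03, mean 0.08, adjusted p = 0.637 over 16 genes), with Cst3 at 552 ± 430 and 458 ± 290 FPKM. T and NK cell genes (median -0.10 over 17 genes, adjusted p = 0.355), mast cell and basophil genes (median -0.04 over 10 genes, adjusted p = 0.165) and stromal and endothelial genes (median -0.0019 over 5 genes, adjusted p = 0.305) were not called either. Nkg7 and Lat of the T and NK list had 199 ± 69.6 and 157 ± 18.3 FPKM and 25.2 ± 7.25 and 19.8 ± 6.92 FPKM. Nkg7 is also a member of the granulocyte-monocyte differentiation list, so its level does not mark T and NK cells alone. The basophil protease genes Prss34 and Mcpt8 had 64.2 ± 49.1 and 61.3 ± 30.3 FPKM and 43.7 ± 33.0 and 47.5 ± 28.3 FPKM. The endothelial gene Pecam1 had 20.6 ± 9.59 and 24.6 ± 9.27, and the pericyte gene Pdgfrb had a log2 fold change of 0.27 (SE 0.84). The neutrophil and T and NK lists were called lower without Metrn cKO 1 (adjusted p = 4.6e-23 and 9.5e-06) or Metrn f/f 1 (4.3e-05 and 0.0027) and higher without Metrn cKO 2 (3.0e-09 and 0.0050) or Metrn f/f 2 (1.1e-08 and 4.1e-05). The dendritic list was called lower without Metrn cKO 1 (adjusted p = 3.4e-07) and higher without Metrn cKO 2 (2.4e-07) or Metrn f/f 2 (5.7e-05).

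Of the 32 lists tested by camera, 16 were called (11 lower, 5 higher), and 0 were called with an estimated correlation, by fry for a change in 1 direction or by fry for a change in either direction. The test with an estimated correlation had little power with 4 libraries, so its lost calls do not show what undid them. Other divisions of the 4 libraries into pairs also called lists: 11 for Metrn f/f 1 and Metrn cKO 1 against the rest and 17 for Metrn f/f 1 and Metrn cKO 2 against the rest. The median over a list was lower in each Metrn cKO library than in each Metrn f/f library for 3 of the 32 lists (immediate early, quiescence and p53 targets). It was higher for 2 (multipotent and lymphoid priming, and cholesterol synthesis). Both counts are below the 16.7% of lists in each direction that chance gives. Only the immediate early and the quiescence list kept their call and direction when each library was left out in turn. The quiescence list is not a separate case, since without the 7 genes shared with the immediate early list its median was 0.08 (camera, adjusted p = 0.70).

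**Figure D3:**
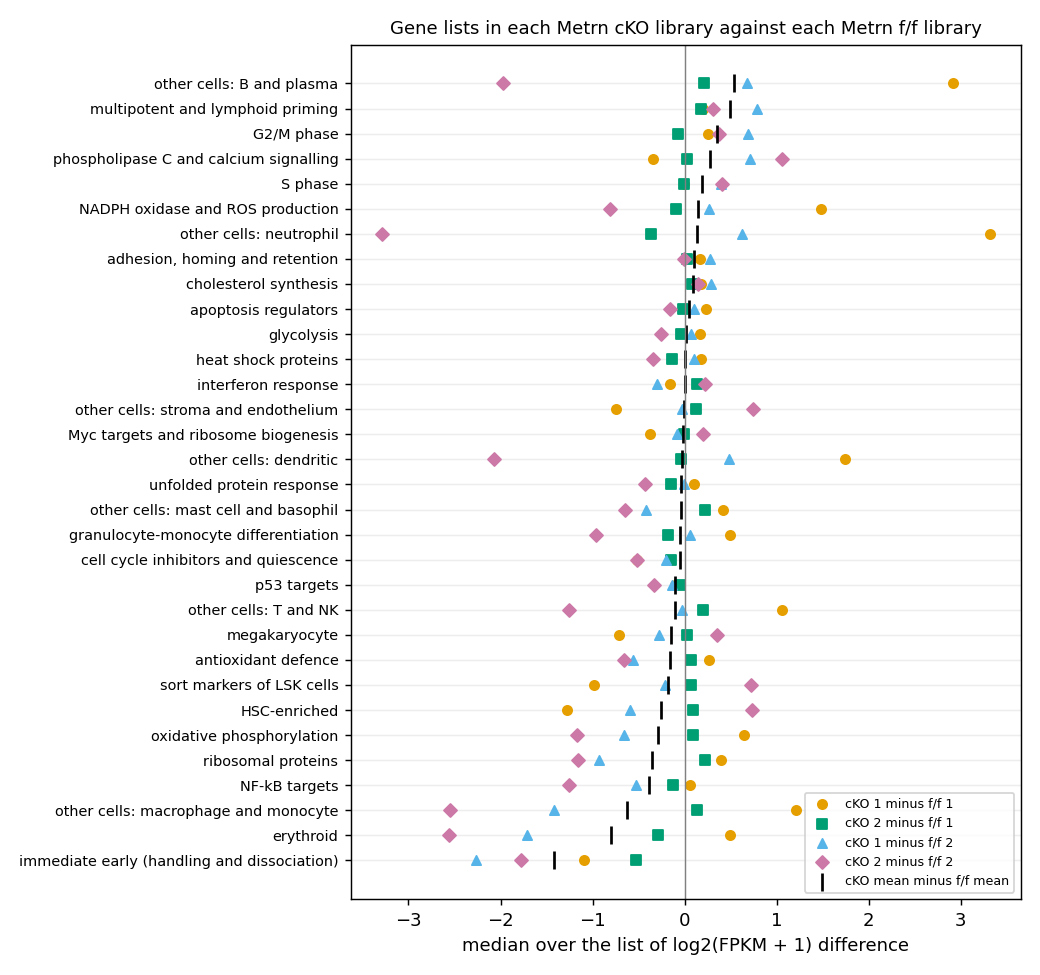
Median over each of the 32 lists of the difference in log2(FPKM + 1) between each Metrn cKO library and each Metrn f/f library (coloured points), with the median log2 fold change of the means as a black bar, on a linear axis. For the immediate early list the 4 points lie between -2.27 and -0.53, and for the neutrophil list they lie between -3.29 and 3.32.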

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

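The scaling alternatives, the crossed numbers and the fit without the length trend were chosen after the data were seen. Pseudocounts of 0.1 and 0.5, a minimum of 0.1 FPKM and the removal of sex-linked genes changed no call and no direction, and 0 genes passed under each of them, under no filter, under an adjusted p of 0.10 and under every scaling. The immediate early list was called lower under each alternative in which its p was computed, except an estimated correlation and fry, which called 0 lists. The replicate numbers showed no pairing (correlation of deviations -0.71 across genes, which are not independent). With the replicate block 3 genes were higher, all of them immunoglobulin variable segments, 1 was lower (Nr4a1) and 18 lists were called, among them NADPH oxidase genes (higher, adjusted p = 0.00282) and unfolded protein response genes (lower, adjusted p = 0.0290), which were not called without it. With crossed numbers as pairs, 37 genes were higher, 65 lower and 18 lists called. These pairs follow the likeness of the libraries in the same values and no label, so the counts are no evidence of change. The median log2 fold change of all genes was 0.07, and it was 0.15 with a fixed sum per library, 0.02 with quantile normalization and 0.01 without the length trend. Without both Metrn f/f 2 and Metrn cKO 1, 1 library remains per genotype and no test was possible. The alternatives planned for read counts (other size factors, count filters and count tests) were not run. Depth is not known, and its ratio between libraries is a hint only, which limits every statement on low genes.

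List calls were lost with no filter (HSC-enriched, megakaryocyte, antioxidant, p53 and B cell lists, adjusted p from 0.119 to 0.236), without the length trend (oxidative phosphorylation 0.0667, antioxidant 0.138) and with quantile normalization (antioxidant 0.148). Calls appeared for NADPH oxidase genes with a fixed sum (0.00539) and quantile normalization (0.00535), for unfolded protein response genes with a fixed sum (0.0413), for Myc targets without the length trend (0.0255), and for NADPH oxidase and Myc targets at a threshold of 0.10. Some directions reversed, in genes and lists that were not called. With a fixed sum per library, the log2 fold changes were 0.0422 for Mpo, 0.0857 for Adgrg1 and 0.0496 for Fdps, and glycolysis had adjusted p = 0.975. Upper quartile scaling gave 0.00045 for Adgrg1. Quantile normalization gave 0.28 for Mpo, 0.0468 for Cyba, 0.15 for Adgrg1, 0.0359 for Fdps and -0.21 for S100a9, with adjusted p = 0.772 for granulocyte-monocyte, 0.735 for glycolysis and 0.774 for heat shock genes. Without the length trend Cyba had 0.15, Hspa8 -0.0657 and Cst3 0.0835, with adjusted p = 0.903 for adhesion and 0.591 for T and NK genes. With no filter T and NK genes had adjusted p = 0.968, and with fry apoptosis genes had 0.991. The cause was not tested.

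Leaving out each library in turn gave 0 to 32 genes higher, 0 to 5 lower and 15 to 19 lists. Besides Metrn and Lyz2, the ranges below are for genes whose direction reversed. Others moved widely within 1 direction, such as Ighg2c (1.20 to 4.44), Igkv5-48 (2.105 to 6.62) and Pdzk1ip1 (-1.93 to -0.0264). With fewer samples, the log2 fold change ranged from -0.735 to 0.415 for Metrn and from -1.77 to 1.79 for Lyz2. Among stem and progenitor genes it ranged from -0.326 to 1.31 for Flt3, -0.974 to 0.418 for Cd34, -1.66 to 0.194 for Esam, -0.862 to 0.851 for Adgrg1 and -0.456 to 0.357 for Mpo. Among lineage genes it ranged from -1.23 to 0.0301 for Gp9, -3.03 to 0.0977 for Klf1, -2.23 to 2.57 for S100a9, -2.23 to 2.79 for S100a8, -0.772 to 0.939 for Prss34, -0.624 to 1.05 for Mcpt8, -0.121 to 2.15 for Ebf1, -0.782 to 3.4 for Ighm, -0.661 to 0.0665 for Nkg7, -1.79 to 1.36 for Cd74 and -1.06 to 0.722 for Cst3. For macrophage and stromal genes the ranges were -2.94 to 0.0481 for Cd14, -2.19 to 0.529 for Cd68, -2.96 to 0.993 for Hmox1, -3.78 to 1.27 for C1qb, -0.194 to 0.745 for Pecam1 and -0.684 to 1.22 for Pdgfrb. For cycle and metabolic genes they were -0.245 to 2.07 for Mki67, -1.16 to 0.0655 for Atp5g1, -1.27 to 0.165 for Ndufa7, -0.899 to 0.0196 for Ndufs7, -0.601 to 0.227 for Aldoa, -0.0776 to 0.39 for Pkm, -1.36 to 0.099 for Gpx4, -1.25 to 1.03 for Cyba, -0.129 to 0.925 for Srebf2, -0.535 to 0.452 for Fdps and -1.24 to 0.133 for Rps27a. For the remaining genes they were -0.396 to 0.684 for Rac2, -0.0435 to 1.27 for Plcg2, -0.875 to 0.182 for B2m, -1.15 to 0.415 for Bax, -0.451 to 0.0753 for Hspa5, -0.295 to 0.328 for Hspa8 and -0.161 to 0.241 for Hsp90ab1.

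The adjusted p of lists that reversed ranged in the same fits from 3.53e-09 to 0.414 for HSC-enriched, 2.84e-07 to 0.956 for multipotent and lymphoid, 8.3e-06 to 0.0138 for granulocyte-monocyte, 7.13e-17 to 0.0304 for erythroid and 0.0358 to 0.964 for LSK sort genes. It ranged from 2.59e-20 to 0.932 for oxidative phosphorylation, 0.457 to 0.826 for glycolysis, 1.12e-05 to 0.889 for antioxidant, 3.2e-08 to 0.749 for NADPH oxidase, 0.000175 to 0.427 for phospholipase C, 6.09e-21 to 0.452 for ribosomal protein, 0.163 to 0.964 for cholesterol and 0.00162 to 0.924 for Myc target genes. It ranged from 0.0417 to 0.821 for adhesion, 0.18 to 0.956 for interferon, 0.0753 to 0.427 for apoptosis and 0.0318 to 0.427 for heat shock genes. For other cells it ranged from 1.56e-17 to 0.801 for macrophage, 4.61e-23 to 4.31e-05 for neutrophil, 7.63e-40 to 0.115 for B and plasma, 9.54e-06 to 0.00498 for T and NK, 0.0529 to 0.658 for mast cell, 2.38e-07 to 0.115 for dendritic and 0.0823 to 0.924 for stromal genes.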

Other observations

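The genotype comparison, the gene lists, Igkv5-48 and S100a8 were planned, and the other tests and genes in this part were chosen after the results were seen. Immunoglobulin transcripts differed widely between libraries. Igkc, the kappa light chain constant gene, had 27.8 FPKM in Metrn f/f 1, 2317 in Metrn f/f 2, 6676 in Metrn cKO 1 and 71.4 in Metrn cKO 2. In Metrn cKO 1 single variable segments reached high levels, with Ighv11-2 at 1034 FPKM and Igkv5-48 at 389, against 36.6 and 14.7 in Metrn f/f 2, and both were listed at 0 in Metrn f/f 1. Short variable segments share reads, so their levels are uncertain. Prg2, the eosinophil major basic protein, had 67.0, 1717, 1301 and 117 FPKM, and Epx, the eosinophil peroxidase, had 9.27, 62.2, 80.2 and 13.9. The albumin gene Alb had 20.7, 0, 5.67 and 30.1 FPKM and Apoa1 had 4.23, 0, 0.955 and 4.61. The stem cell transcription factor genes Hlf (38.7, 9.33, 6.94 and 47.6 FPKM) and Mecom (6.99, 1.38, 1.20 and 7.40) followed Kit.

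Of the genes with both Metrn cKO values above (829) or below (754) both Metrn f/f values, fewer in each direction than the 16.7% chance gives, a few are described here, and none of these passed the test. Plpp6, a lipid phosphatase, was listed at 0 in both Metrn f/f libraries and had 3.95 and 6.42 FPKM in Metrn cKO. Cygb, a globin of fibroblasts and other cells, had 0.174 and 0.0216 FPKM in Metrn f/f and 3.51 and 2.40 in Metrn cKO. The microRNA genes Mir23a, Mir27a and Mir24-2, neighbours on chromosome 8 between positions 84208518 and 84208921, had log2 fold changes of -1.62 (SE 0.61), -1.63 (SE 0.54) and -2.18 (SE 0.69), n = 2 each. Such values come from reads over the hairpin region and do not measure mature microRNA. Rgs1, a regulator of G protein signalling that is induced by activation, had 250 ± 224 and 42.3 ± 33.1 FPKM, and the chemokine gene Ccl4 had 127 ± 120 and 27.5 ± 11.6.

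Mature cell transcripts were high in Metrn f/f 2 and Metrn cKO 1, that is within each genotype, so genotype as labelled was not weighed. A trend with transcript length is argued against as the whole cause, since the neutrophil list still differed by 2.21 (3.02 before) between the Metrn f/f libraries and by 3.51 (3.56 before) between the Metrn cKO libraries once it was removed. Mature marrow cells in the sorted fraction, which the lineage gate is meant to remove, remain an open and untested source: 6 of 6 mature lists had higher medians in both libraries, and the LSK sort markers lower ones (Ly6a was not lower), but that restates the pattern. S100a8 reached 9998 FPKM in Metrn f/f 2 and 19009 in Metrn cKO 1, Hba-a1 reached 12452 and 10354, and of the 110 genes of these lists 81 also reached 1 FPKM in both other libraries and 1 stood in more than 1 list. Of the 3 ways to divide the libraries into pairs, the division of Metrn f/f 2 and Metrn cKO 1 from the rest called 1594 genes, which restates the likeness it was drawn from, while the genotypes and the remaining division called 0 each, and whether labels were exchanged was not tested.

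Immediate early genes were lower in both Metrn cKO libraries. Mature cell content cannot be excluded as the cause by Metrn cKO 1, which held more mature cell transcripts than Metrn f/f 1. It lay below Metrn f/f 1 by a median of -1.09, with 21 of 24 genes lower. The HSC-enriched genes and LSK sort markers lay below in this pair too, by -1.28 and -0.99, so a smaller LSK share could lower the list. Metrn f/f 2, also rich in mature cell transcripts, lay above Metrn f/f 1 by 1.32. In the closest pair, Metrn cKO 2 lay below Metrn f/f 1 by -0.53, with 23 of 24 genes lower, while the HSC-enriched list differed by 0.09. Transcript length is argued against, since the median log2 fold change was -1.44 with the trend removed (19 of 24 genes still lower in both). The time between killing, sorting and lysis could set these genes in every cell type and cannot be told apart from genotype, because 0 of the 4 libraries have a label for day, batch or order. An effect of the genotype on these genes remains open and untested for the same reason.

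Ribosomal protein and respiratory chain genes were high in Metrn f/f 2, by a median of 1.36 above Metrn f/f 1 over 135 genes. Neutrophil content is argued against, since Metrn cKO 1, with a neutrophil median 0.62 higher, lay below Metrn f/f 2 by a median of -0.86, with 97.0% of the genes lower, but erythroid and macrophage genes were also highest in Metrn f/f 2 (medians 2.57 and 2.79 above Metrn f/f 1) and were not tested as a source. A trend with transcript length is a candidate cause of a large part: fitted on all other genes and removed, it left 0.59. Across 12426 genes, which are not independent, the difference between Metrn f/f 2 and Metrn f/f 1 had a Spearman rho of -0.66 and a Pearson r of -0.51 with transcript length, and the median was 0.97 for transcripts under 1000 nt and -1.31 for those over 5000 nt. Such a trend is consistent with RNA or library quality, which was not tested, and a biological cause was not tested either.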
